A study of Mus musculus with 12 samples.

How the data were processed

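Total RNA of mouse embryonic stem cells was hybridised to 12 single-colour (Cy3) Agilent arrays, 3 for each combination of genotype (wild type or Nat1-null) and medium (LIF or 2i+LIF). Cells were grown on gelatin-coated plates per the labels. Per the file headers, the deposited scanner files hold intensity values (processed signal, and median pixel signals of spots and local background) made by Agilent Feature Extraction 10.7.3.1, which subtracts background and removes spatial trends within an array and does not scale between arrays. The authors' deposited series table holds log2 values of the processed signal shifted so that the 75th percentile of each array is 0; these were recomputed from the scanner files and correlated with them at 1 on each array. The scanner files carry no gene symbols. Probes were named through RefSeq transcript accessions and an annotation of assembly GRCm38.p6, which gave a symbol to 27656 of 55681 probes, including 98.7% of those designed to curated RefSeq mRNAs.

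For the main values, the processed signal was put on the log2 scale, control spots and spots marked as outliers by the scanner program were removed, the spots of a probe were averaged, and the 75th percentile of each array was subtracted. Of 55681 probes, 54229 had a value on all 12 arrays, and 33293 of them were kept because they were well above background on all arrays of at least 1 group. One probe stood for each gene, the one with the highest mean over all arrays, which left 24463 genes. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 4 groups with moderated variances, and 6 contrasts were tested, two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and calls at adjusted p below 0.05. Counts "by at least 2-fold" also needed an absolute log2 difference of 1. A fold against a group in which a gene was not well above background on any array was computed against the lowest single spot well above background on each array of that group (or the gene's own value where higher) and is given as "at least". A difference without that wording from a gene near background depends on the background subtraction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

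Before the data were examined, 25 gene lists were fixed: naive pluripotency, general pluripotency, formative and primed epiblast, ERK pathway targets, MAPK pathway components, Wnt and beta-catenin targets, LIF and STAT3 targets, Nodal, BMP and TGF-beta targets, primitive streak and mesoderm, endoderm, neural ectoderm, trophoblast, 2-cell embryo genes, germline genes, DNA methylation machinery, Polycomb group, translation initiation factors, cytosolic ribosomal proteins, ATF4 and integrated stress response, unfolded protein response, p53 targets, cholesterol synthesis, glycolysis, G1 and cell cycle control, and fibroblast and feeder cell markers. Lists overlap in single genes (Tfcp2l1, Klf4, Gbx2, Dnmt3b, Cdx1 and Myc, among others, stand in more than 1). camera tested whether a list shifted relative to other genes with a preset correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the residuals; of 71 calls, 9 also passed with the estimated correlation. The estimate comes from 12 arrays and makes the test far more cautious, also for lists whose estimated correlation is not above the preset one or is close to it. For genotype in LIF, the 2-cell embryo genes (estimate -0.053) went from camera adjusted p = 5.9e-05 to 0.029. Neural ectoderm (estimate 0.012) went from 1.7e-04 to 0.029. A call lost in this setting thus does not by itself show that the genes of the list vary together. Further lists (imprinted genes, Hox paralogs 1 to 8 and 9 to 13, smooth muscle contractile genes, and Y-linked genes) were chosen after the data were seen.

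The rule for which genes are named was also fixed in advance. For each comparison it takes Eif4g2, a fixed set of pluripotency, signalling and lineage genes whatever their values (of these, T was not tested because its probe did not pass the filter), the 6 largest rises and 6 largest falls among bright called genes whose groups do not overlap, the 3 largest rises and falls among called genes not well above background in the lower group, and up to 4 called members of each list with the largest differences. For the interaction the largest values were taken among genes bright on all 12 arrays. The value of 1 gene that the rule takes is not reported here; the gene stays in the fits and lists. Further genes named in the closing section were chosen after their values were seen.

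The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples only. Replicate numbers gave little sign of pairing across groups, with 1 exception. Residuals correlated above 0.1 in 1 of 18 pairs with the same number, replicate 2 of the Nat1-null groups (0.301). Of 12 arrays, 2 correlated best with an array of their own number. The main fit pairs no arrays, and a pairing of the Nat1-null groups alone was not tested. Alternatives were normexp background correction (on median spot signals with an offset of 50, because the files lack the mean signals that had been planned), quantile normalization, no scaling between arrays, no filter on dim probes, only probes well above background on all 12 arrays, the mean of a gene's probes, every probe on its own, the authors' series values, eBayes with trend and robust settings, the replicate number as a block, only the 6 arrays compared, and leaving out each array in turn. The slide row as a block was added after the data were seen; it compares the Nat1-null 2i+LIF arrays with 1 Nat1-null LIF array.

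The pipeline was tested on simulated data, drawn around the mean of each gene with the spread fitted to the real arrays, in which 50 genes at each of 4 sizes were changed in 1 group. It recovered 42% of changes of 0.5 on the log2 scale, 72% of 1, 96% of 2 and 98% of 3, and called 6 of 24263 unchanged genes. Correlations between comparisons are across genes, and overlaps of calls between comparisons that share no arrays were tested with Fisher's exact test. Array values give no read depth; signal over background sets what can be measured, and 49.8% to 66.3% of gene-directed spots were well above background.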

Results

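RNA levels were measured on 12 single-colour Agilent microarrays of mouse embryonic stem cells. The arrays form 4 groups of 3: wild-type cells in LIF, wild-type cells in 2i+LIF, Nat1-null cells in LIF, and Nat1-null cells in 2i+LIF. LIF is a cytokine that keeps mouse embryonic stem cells undifferentiated through STAT3, and 2i is a pair of inhibitors of MEK (in the ERK pathway) and of the kinase GSK3, whose inhibition turns on Wnt target genes. Nat1 is taken here as the older name of Eif4g2 (DAP5), a translation factor of the eIF4G family, and not as the mouse gene whose present symbol is Nat1, an N-acetyltransferase. Of 59305 gene-directed spots, between 49.8% and 66.3% were well above background on each array. After filtering, 24463 genes were tested, 15428 of them with a symbol. The number of arrays limits the precision, and replicate arrays correlated at 0.988 or more across genes. Nat1-null replicates differed more from each other than wild-type ones. The SD across genes of the difference between 2 replicates was 0.483 to 0.581 in Nat1-null groups and 0.254 to 0.313 in wild-type groups. Each level below is a log2 signal relative to the 75th percentile of its array, and n = 3 throughout.

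The arrays lie on 3 slides. All wild-type LIF arrays are on slide 1, all wild-type 2i+LIF arrays are on slide 2, and all Nat1-null arrays are on slide 3. The genotype and the medium of wild-type cells therefore cannot be told apart from the slide, and the comparison of media in Nat1-null cells is the single one made within a slide. On slide 3, the third Nat1-null LIF array and the 3 Nat1-null 2i+LIF arrays share a row and had negative-control means from -16.4 to -10.2, outside the scanner program's accepted range.

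Eif4g2 RNA was 9.28-fold lower in Nat1-null than in wild-type cells in LIF and 7.42-fold lower in 2i+LIF. Its mean level was 4.49 ± 0.05 (SD, n = 3) in wild-type LIF, 4.20 ± 0.10 in wild-type 2i+LIF, 1.28 ± 0.04 in Nat1-null LIF and 1.31 ± 0.10 in Nat1-null 2i+LIF. The signal stayed well above background on all 6 Nat1-null arrays, and the files do not say which part of the gene was deleted relative to the single probe. The probe for the gene now called Nat1 was dim, with a mean signal of 92.3 units in wild-type LIF and 19.3 units in Nat1-null LIF. In 2i+LIF its mean was 37.6 units in wild-type and 35.8 units in Nat1-null cells. It was well above background on 0 of 3 Nat1-null LIF arrays.

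**Figure D1:**
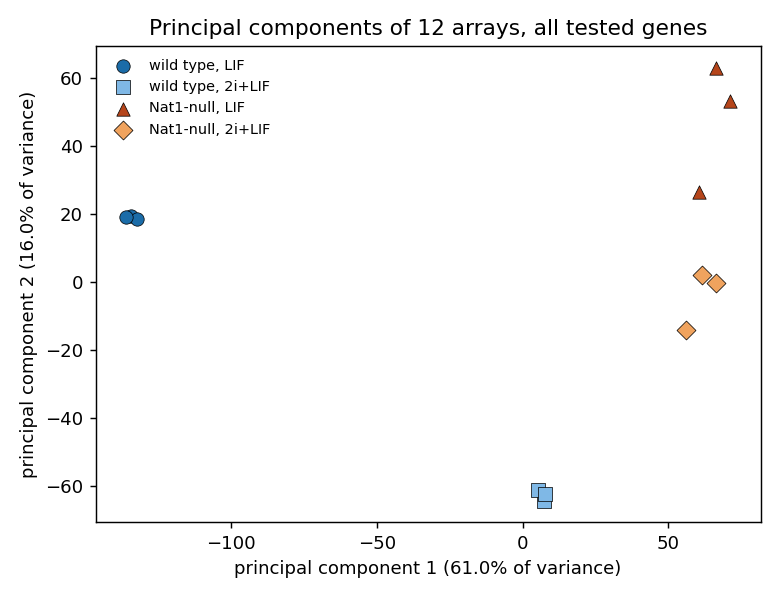
Principal components of the 12 arrays over all 24463 tested genes; each point is an array and its colour and shape give its group. The first component carries 61.0% of the variance and parts the wild-type LIF arrays from the other groups, and the second carries 15.98%.

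The first comparison asks what 2i does to wild-type cells. Several genes of the naive, preimplantation-like state of pluripotency rose: Tfcp2l1, a transcription factor downstream of STAT3, by 14.9-fold, Nanog by 3.98-fold, and Esrrb, Klf4, Prdm14 and Klf2 by 2.30, 1.95, 1.98 and 1.61 on the log2 scale. Nanog went from 2.31 ± 0.03 to 4.31 ± 0.02. Among targets of ERK signalling the early-response transcription factor Egr1 was lower by 55.2-fold and the ERK phosphatase Dusp6 by 6.02-fold, while the ETS factor Etv5 rose by 0.89 and its relative Etv4 (0.08) did not pass. Egr1 in 2i+LIF (-4.60, -4.80 and -4.78) was near the lowest spot well above background on each array (-5.30, -5.06 and -4.64). The size of its differences from wild-type 2i+LIF, here and below, thus depends on the background subtraction. Cdx1, a homeobox gene and Wnt target, had the largest rise among bright genes, 61.8-fold, from -1.76 ± 0.03 to 4.19 ± 0.04. The Wnt and beta-catenin targets as a list were not called (4 up, 8 down of 20, adjusted p = 0.29), and Axin2, a feedback inhibitor of Wnt signalling, did not pass (0.02). Fgf5, a marker of the formative epiblast, was at least 10.5-fold lower, since it was not well above background in 2i+LIF.

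Among the fixed gene lists, naive pluripotency had 15 of 20 tested genes up and 2 down. Its 2 exceptions were Dppa3, a germline and preimplantation gene that fell by 3.98, and Gbx2, which fell by 2.20. The list passed at adjusted p = 1.6e-04, and at adjusted p = 0.37 with an estimated correlation did not. Glycolysis had 23 of 23 genes up, among them Aldoc, an aldolase, by 3.23 and Slc16a3, a lactate transporter, by 2.25 (adjusted p = 6.7e-08; adjusted p = 0.34 with an estimated correlation). Cholesterol synthesis had 16 of 24 up and 0 down, with Insig1, a sterol sensor, up by 1.37 (adjusted p = 2.6e-04; adjusted p = 0.37 with an estimated correlation). ERK pathway targets had 14 of 22 down and 3 up (adjusted p = 4.3e-04; adjusted p = 0.27 with an estimated correlation).

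Several lists of differentiating cells and the 2-cell embryo genes were lower in 2i+LIF. Apart from trophoblast, these calls also passed with an estimated correlation, each at adjusted p = 0.015. Formative and primed epiblast had 14 of 18 genes down and 0 up, among them Pou3f1, a POU transcription factor, by -4.35 and the DNA methyltransferase Dnmt3b by -2.56. Neural ectoderm had 17 of 19 down, with Fabp7, a lipid carrier of neural progenitors, at least 88.6-fold lower. Fibroblast and feeder cell markers had 14 of 18 down, with smooth muscle actin Acta2 lower by 267-fold and the collagen gene Col1a2 by -7.61. The 2-cell embryo genes had 13 of 16 down. Trophoblast had 11 of 17 down, with the simple-epithelium keratins Krt8 and Krt18 at -5.18 and -5.89 (adjusted p = 0.0051; adjusted p = 0.28 with an estimated correlation; 0.17 without scaling between arrays).

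The Nodal, BMP and TGF-beta targets had 9 of 18 down and 3 up, with the antagonist Lefty1 at -2.78, and p53 targets had 13 of 23 down and 5 up. Both calls ended with an estimated correlation, at adjusted p = 0.27 and adjusted p = 0.37, and without scaling, at adjusted p = 0.26 and adjusted p = 0.28. Cytosolic ribosomal proteins had 56 of 73 up by a median of 0.27, but their call ended with quantile normalization at adjusted p = 0.59, ended with an estimated correlation at adjusted p = 0.60, and turned downward without scaling. Adjusted over the list alone, the counts named for this comparison changed by at most 1 gene per direction. The largest rises that the naming rule took from all genes included the posterior Hox genes Hoxa10, at least 15.9-fold, Hoxa11, at least 9.01-fold, and Hoxc11, at least 8.08-fold, with Ndufa4l2, a mitochondrial subunit induced by low oxygen, at 5.15.

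In this comparison 15227 of 24463 genes passed limma at adjusted p below 0.05, of which 8565 were higher in 2i+LIF and 6662 lower. By at least 2-fold, 1755 rose and 2935 fell, a total of 4690 that became 2638 with normexp background correction and 2569 among probes bright on all 12 arrays. Without scaling between arrays the median difference of all genes moved by -0.57 and 12.8% of called genes were higher, against 56.2% with scaling.

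The second comparison asks what loss of Nat1 does in LIF. Several naive genes were again higher: Tfcp2l1 by 8.31-fold, Nanog by 2.64-fold, and Klf4, Esrrb and Prdm14 by 3.00, 2.36 and 2.39 on the log2 scale. The core factors Pou5f1 and Sox2 rose by 1.44 and 2.01. Several genes of contractile and matrix-forming cells were lower, with Acta2 lower by 789-fold, Col1a1 at -7.25 and cardiac actin Actc1 at least 672-fold lower. Dppa3 was 103-fold lower, from 3.77 ± 0.02 to -2.91 ± 0.08. ERK targets did not move together: Egr1 was 8.90-fold lower, while the ERK feedback inhibitor Spry4 and Etv4 were higher by 2.32 and 2.40. Dusp6 was higher by 0.50, which did not pass without scaling (adjusted p = 0.060) or without Nat1-null LIF replicate 1 (0.059) or 3 (0.063).

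The naive pluripotency list had 17 of 20 genes up and 2 down (adjusted p = 3.8e-05; adjusted p = 0.29 with an estimated correlation). LIF and STAT3 targets had 14 of 18 up, with Socs3, the feedback inhibitor of STAT3, at 2.79 (adjusted p = 3.2e-04; adjusted p = 0.29 with an estimated correlation). Glycolysis had 19 of 23 up and 0 down (adjusted p = 3.7e-06; adjusted p = 0.37 with an estimated correlation). The unfolded protein response had 16 of 21 up, with the endoplasmic reticulum proteins Derl3 at 2.50, Sdf2l1 at 1.58 and Hyou1 at 1.35 (adjusted p = 3.1e-04; adjusted p = 0.29 with an estimated correlation).

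Fibroblast and feeder cell markers had 17 of 18 genes down, with a median of -4.17, and neural ectoderm had 15 of 19 down, with Nes, an intermediate filament of neural progenitors, at -4.61. The 2-cell embryo genes had 13 of 16 down, with Zscan4c at -5.97 and Pramel6 at least 119.6-fold lower. These 3 calls passed with an estimated correlation, each at adjusted p = 0.029. Formative and primed epiblast had 13 of 18 down (adjusted p = 0.0034; adjusted p = 0.16 with an estimated correlation), and trophoblast had 13 of 17 down, with Gata3, a trophoblast transcription factor, at -4.96 (adjusted p = 0.0082; adjusted p = 0.29 with an estimated correlation). The p53 targets had 15 of 23 down, with the death receptor Fas at -3.33 (adjusted p = 0.0022; adjusted p = 0.29 with an estimated correlation). Germline genes had 12 of 24 down and 4 up at adjusted p = 0.048, which ended without scaling at adjusted p = 0.087, with the mean of a gene's probes at adjusted p = 0.059 and with an estimated correlation at adjusted p = 0.72; leaving out any wild-type array, Nat1-null LIF replicate 1 or 3, or Nat1-null 2i+LIF replicate 3 ended it too, at adjusted p up to 0.085, without Nat1-null LIF replicate 1. The named counts in this comparison were the same when adjusted over the list alone.

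Outside the lists, the homeobox gene Nkx6-3 at 6.35, 1600014C23Rik at 6.32, Islr2 at 6.27, and the activin subunit Inhbb at 5.56 had the largest rises, and the neuropeptide precursor Vgf was among the largest falls at -6.73. Map3k3, a kinase of the MAPK pathways, rose by 0.21, a call that ended without scaling (adjusted p = 0.54), and Sos1, an activator of Ras, did not pass (0.33, adjusted p = 0.58), a value that rests on wild-type LIF replicate 2: without it the difference was 1.06 (adjusted p = 8.1e-04), and without replicate 1 or 3 it was -0.03 or -0.04. In all, 16349 genes passed, 8294 higher and 8055 lower in Nat1-null cells. By at least 2-fold, 2419 rose and 3941 fell, a total of 6360 that became 4215 with normexp background correction and 3735 among probes bright on all 12 arrays. Without scaling the median of all genes moved by -0.15 and 39.3% of called genes were higher, against 50.7%.

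**Figure D2:**
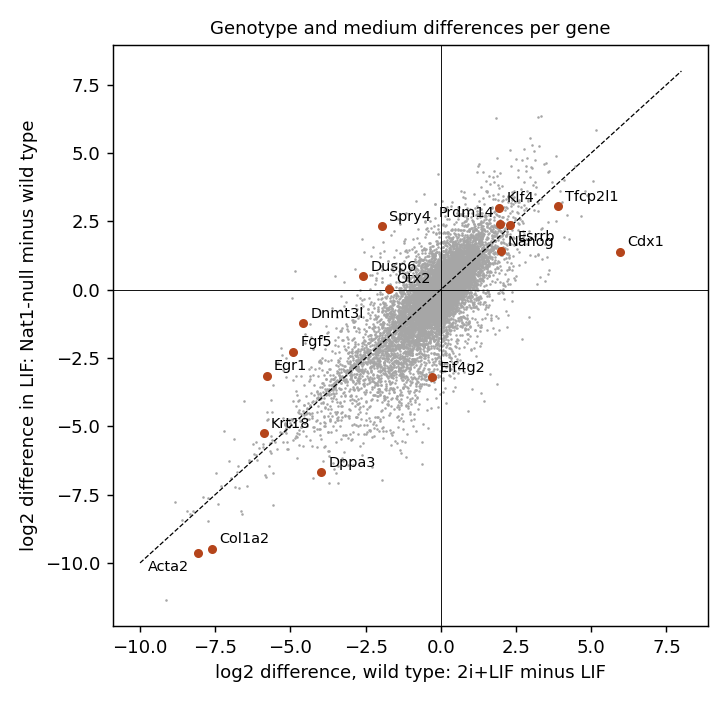
Log2 difference of each named gene between Nat1-null and wild-type cells in LIF (vertical) against its log2 difference between 2i+LIF and LIF in wild-type cells (horizontal). Each grey point is a gene, named genes are in red, the dashed line marks equal differences, and over all tested genes the correlation is 0.790.

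Nat1-null cells in LIF and wild-type cells in 2i+LIF differed from wild-type cells in LIF largely in the same direction. Nanog, Klf4, Esrrb, Tfcp2l1 and Prdm14 were higher, and Acta2, Col1a2, Krt18, Egr1, Dnmt3b and Dppa3 were lower, in both comparisons. Of 11952 genes called in both, 92.1% had the same sign, and of 3482 genes changed at least 2-fold in both, 97.9% did. Rises were shared by 6004 genes and falls by 5004. The differences correlated across genes at Pearson's r = 0.790 and Spearman's rho = 0.726. Genes are not independent replicates, and both comparisons share the wild-type LIF arrays. Those arrays alone gave 100 simulated unchanged pairs a mean r of 0.446 (up to 0.895). In these pairs 64.8% of all genes had the same sign (up to 89.4%), while the 92.1% above is over called genes only. The covariance was 1.09, against a mean of 0.0277 and at most 0.0688 in those pairs. Of 4 pairs of comparisons examined in this way, the genotype differences in LIF and in 2i+LIF correlated at 0.407 (rho 0.390, 79.5% of 8342 shared calls with the same sign). They share no arrays, but all Nat1-null arrays and no wild-type arrays lie on slide 3. An effect of that slide would enter both differences with the same sign and cannot be told apart from the genotype. The genotype differences in 2i+LIF and the 2i differences of Nat1-null cells correlated at 0.301 (rho 0.251, 68.0% of 5046 shared calls with the same sign). Both hold the Nat1-null 2i+LIF arrays, and how much of this those arrays alone would give was not tested.

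The third comparison asks what loss of Nat1 does when 2i is present. Several genes of ERK signalling and of the epiblast were higher in Nat1-null cells: Spry4 by 2.33, Egr1 by 3.16-fold, Etv4 by 1.61, Dusp6 by 2.39-fold, Otx2, an epiblast transcription factor, by 1.36, and Dnmt3l, a cofactor of DNA methylation, by 1.70. Fgf5 was at least 5.70-fold higher. Among naive genes Tfcp2l1 and Klf4 rose by 0.73 and 0.87, Nanog was at -0.42, a call that ended without scaling (adjusted p = 0.069), and Esrrb, Prdm14, Zfp42, Klf2 and Dppa3 did not pass. Snrpn, a paternally expressed imprinted gene, had the largest fall at -4.92, and the imprinted noncoding RNA Kcnq1ot1 was at -3.85.

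ERK pathway targets had 16 of 22 genes up and 0 down (adjusted p = 6.4e-05), and the unfolded protein response had 15 of 21 up, with the chaperone Hspa5 at 0.65 (adjusted p = 1.5e-05). LIF and STAT3 targets had 12 of 18 up, with Socs3 at 1.00 (adjusted p = 4.6e-04). These ended with an estimated correlation, at adjusted p = 0.22, adjusted p = 0.22 and adjusted p = 0.24. Trophoblast had 11 of 17 up, with Gata2 at 2.97 and Krt18 at 1.88 (adjusted p = 0.0010; adjusted p = 0.22 with an estimated correlation), the opposite direction to LIF. General pluripotency had 9 of 20 up and 1 down, with Foxd3 at 2.45 and Sox2 at 0.95 (adjusted p = 0.0066; adjusted p = 0.59 with an estimated correlation). Primitive streak and mesoderm had 9 of 16 up, with Evx1 at 2.23 and Eomes at 1.47, both transcription factors of the streak (adjusted p = 0.013; adjusted p = 0.30 with an estimated correlation). Glycolysis had 12 of 23 up and 3 down (adjusted p = 0.0090; adjusted p = 0.63 with an estimated correlation).

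Shifts upward were also called for Nodal, BMP and TGF-beta targets (12 of 18 up), Wnt and beta-catenin targets (12 of 20), MAPK pathway components (12 of 26), the Polycomb group (11 of 26) and the ATF4 and integrated stress response (12 of 25). With an estimated correlation they had adjusted p = 0.22, 0.24, 0.22, 0.39 and 0.39 in that order. Without scaling the first pair had adjusted p = 0.065 each and the ATF4 list also adjusted p = 0.065, and among probes bright on all 12 arrays the MAPK and Polycomb lists had adjusted p = 0.074 each. The ATF4 list also ended without wild-type 2i+LIF replicate 3 (adjusted p = 0.053) or Nat1-null 2i+LIF replicate 2 (adjusted p = 0.050), and the Wnt list with the mean of a gene's probes (adjusted p = 0.067). Their highest members included Axin2 at 1.65, Fgfr3 at 2.39, the Polycomb subunits Suz12 at 0.98 and Aebp2 at 0.98, and Atf4 itself at 1.24. The G1 and cell cycle control list was not called in any comparison, and here had 9 of 22 up and 3 down at adjusted p = 0.056. The 2-cell embryo genes were not called as a list (4 up, 8 down, adjusted p = 0.077), while Zscan4c fell by 3.76. Neural ectoderm (3 up, 9 down of 19, adjusted p = 0.10), endoderm (5 up, 11 down of 20, adjusted p = 0.19) and formative and primed epiblast (9 up, 7 down of 18, adjusted p = 0.60) were not called either. Adjusted over the list alone, 14 Polycomb genes, 13 Wnt genes, 12 trophoblast genes, 6 endoderm genes and 16 genes of the unfolded protein response were higher and 9 of the 2-cell genes were lower.

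In 2i+LIF 10666 genes passed, 5133 higher and 5533 lower in Nat1-null cells. By at least 2-fold, 827 rose and 1829 fell, a total of 2656 that became 1218 with normexp background correction and 1411 among probes bright on all 12 arrays. Without scaling the median of all genes moved by 0.22 and 75.9% of called genes were higher, against 48.1%. The largest rises were Tlx2 at 4.21, Fxyd4 at 4.03, Islr2 at 3.47, Nkx6-2 at 3.46, Sting1, an innate immune sensor, at 3.39, and Crb3 at 3.30.

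**Figure D3:**
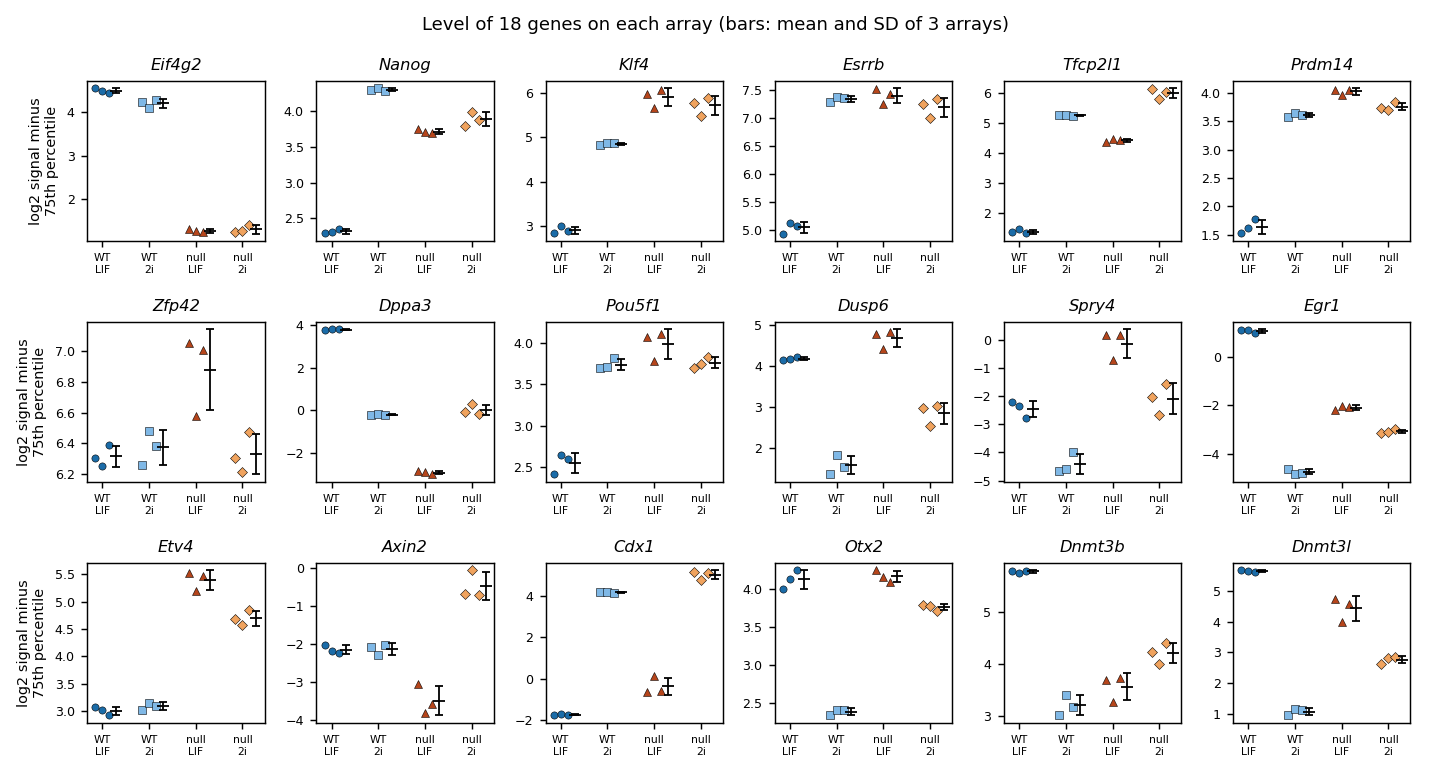
Log2 level of 18 genes on each of the 12 arrays, relative to the 75th percentile of the array, by group (WT, wild type; null, Nat1-null; 2i, 2i+LIF). Bars give the mean and SD of 3 arrays; Nanog is 2.31 in wild-type LIF and between 3.72 and 4.31 in the other groups, while Cdx1 is above 4 in both groups with 2i.

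The fourth comparison asks whether Nat1-null cells respond to 2i, with both groups on a single slide. Several Wnt targets rose: Cdx1 by 42.8-fold, Axin2 by 8.07-fold and Sp5, a direct target of beta-catenin, by 4.70. Among ERK targets Dusp6 was lower by 3.56-fold, Spry4 was at -1.95 and Egr1 was lower by 1.96-fold, while Etv5 (-0.07) did not pass. The naive genes Tfcp2l1 and Dppa3 rose by 1.58 and 2.92, while Esrrb (-0.21) and Klf4 (-0.18) did not pass. The fit did not pair replicate numbers. Klf4 was lower in 2i+LIF at each number (5.98, 5.67 and 6.06 in LIF, 5.79, 5.49 and 5.90 in 2i+LIF). So was Esrrb (7.52, 7.26 and 7.44 in LIF, 7.24, 7.01 and 7.34 in 2i+LIF). Nanog was at 0.17 (adjusted p = 0.037), a call that ended without any array but Nat1-null 2i+LIF replicate 1, at adjusted p up to 0.11 without replicate 2 of that group, and the value was -0.02 without scaling. Plagl1, an imprinted zinc-finger gene, had the largest rise at 5.52. Eif4g2 itself did not pass (0.03, adjusted p = 0.73).

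Wnt and beta-catenin targets had 10 of 20 genes up and 1 down, with Lef1 the exception at -2.52 (adjusted p = 0.0074; adjusted p = 0.42 with an estimated correlation), and primitive streak and mesoderm had 8 of 16 up and 1 down (adjusted p = 0.0074; adjusted p = 0.49 with an estimated correlation). Trophoblast had 11 of 17 up, with Gata3 at 1.83 and Ascl2 at 1.70 (adjusted p = 0.0015; adjusted p = 0.34 with an estimated correlation). The 2-cell embryo genes had 10 of 16 up, with Pramel6 at least 7.96-fold higher (adjusted p = 0.0021; adjusted p = 0.13 with an estimated correlation). Cholesterol synthesis had 16 of 24 up and 1 down (adjusted p = 0.0021; adjusted p = 0.49 with an estimated correlation). General pluripotency had 10 of 20 down and 1 up, with Utf1 at -1.04 and Tdgf1 at -0.69 (adjusted p = 0.0012; adjusted p = 0.49 with an estimated correlation). Formative and primed epiblast had 9 of 18 down and 3 up, with Zic2 at -1.40 (adjusted p = 0.0074; adjusted p = 0.34 with an estimated correlation).

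ERK pathway targets had 8 of 22 down and 1 up (adjusted p = 0.019), p53 targets had 11 of 23 up and 3 down, with Cdkn1a, a cell cycle inhibitor, at 1.55 (adjusted p = 0.020), endoderm had 9 of 20 down and 5 up (adjusted p = 0.042), and the ATF4 and integrated stress response had 12 of 25 down and 5 up (adjusted p = 0.044). With an estimated correlation these had adjusted p = 0.49, 0.49, 0.61 and 0.49. Without scaling the ERK list had adjusted p = 0.11, and within rows of the slide the p53, endoderm and ATF4 lists had adjusted p = 0.13, 0.19 and 0.19. Without Nat1-null LIF replicate 2 these 3 had adjusted p = 0.11, 0.23 and 0.20, and without Nat1-null 2i+LIF replicate 1 the endoderm and ATF4 lists had adjusted p = 0.083 and 0.12. Ribosomal proteins had 60 of 73 up by a median of 0.21, translation initiation factors had 16 of 38 up and 1 down, and glycolysis had 15 of 23 up and 2 down. With quantile normalization these 3 had adjusted p = 0.62, 0.10 and 0.087 (initiation factors 0.056 without Nat1-null LIF replicate 2), and with an estimated correlation adjusted p = 0.49, 0.49 and 0.61. Adjusted over the list alone, 68 ribosomal genes, 17 initiation factors and 11 of the 2-cell genes were higher and 12 general pluripotency genes were lower; the other counts were the same in the direction called.

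In Nat1-null cells 9079 genes passed, 5224 higher and 3855 lower in 2i+LIF. By at least 2-fold, 906 rose and 1052 fell, a total of 1958 that became 974 with normexp background correction and 1157 among probes bright on all 12 arrays. With the 6 arrays alone, and so without the less variable wild-type arrays in the estimate of the spread, 4846 passed. The share of called genes that were higher, 57.5%, was 47.5% with quantile normalization and 22.2% without scaling, which moved the median of all genes by -0.19. With the slide row as a block, an alternative added after the data were seen, 6667 genes passed; that setting rests on the single Nat1-null LIF array that shares a row with the 2i+LIF arrays.

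The interaction asks whether the 2i difference depended on the genotype. It holds the difference between the wild-type groups, which lie on slides 1 and 2, so it cannot be told apart from the slide. Naive genes that 2i raised in wild-type cells rose less or did not rise in Nat1-null cells: the difference of differences was -2.51 for Esrrb, -2.32 for Tfcp2l1, -2.24 for Prdm14, -2.13 for Klf4 and -1.82 for Nanog. Genes that 2i lowered in wild-type cells fell less or rose in Nat1-null cells: Egr1 (4.81), Dnmt3b (3.21), Dnmt3l (2.92), Acta2 (9.33) and Krt18 (7.14). Acta2 was at 6.30 in wild-type LIF and at -1.76, -3.32 and -2.05 in wild-type 2i+LIF, Nat1-null LIF and Nat1-null 2i+LIF. Its interaction thus reflects a high level in wild-type LIF alone. Dppa3, which fell with 2i in wild-type cells and rose in Nat1-null cells, was at 6.90. Axin2 (2.99) rose with 2i in Nat1-null cells and did not pass in wild-type cells (0.02). For Cdx1 (-0.53, SE 0.26) and Spry4 (0.01, SE 0.48) no difference between genotypes was called.

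Of the lists, fibroblast and feeder cell markers (14 of 18 genes with a positive interaction) and 2-cell embryo genes (13 of 16) were shifted upward and passed with an estimated correlation, at adjusted p = 0.030 and adjusted p = 0.022. Trophoblast (12 of 17), formative and primed epiblast (10 of 18), neural ectoderm (12 of 19), p53 targets (14 of 23), Wnt and beta-catenin targets (13 of 20) and ERK pathway targets (10 of 22) were shifted upward too. Their adjusted p with an estimated correlation was 0.062, 0.072, 0.057, 0.23, 0.17 and 0.40. Neural ectoderm ended at adjusted p = 0.25 and ERK targets at adjusted p = 0.13 among probes bright on all 12 arrays. Glycolysis (19 of 23), naive pluripotency (16 of 20) and LIF and STAT3 targets (11 of 18) were shifted downward, with adjusted p = 0.40, 0.32 and 0.40 with an estimated correlation. Adjusted over the list alone, 14 of the 2-cell genes, 13 neural, 15 p53, 11 ERK and 12 LIF and STAT3 genes were called in these directions, and the other counts were the same.

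The interaction was called for 12166 genes, 5769 upward and 6397 downward, and for 4973 by at least 2-fold, which became 3250 with normexp background correction and 3006 among probes bright on all 12 arrays. Without scaling the median moved by 0.37 and 78.5% of the called genes were upward, against 47.4%. Across genes the 2i differences of wild-type and of Nat1-null cells, which share no arrays, correlated at 0.0541 (rho 0.0969), and 62.8% of 6517 genes called in both had the same sign. Shared rises numbered 2630 against 1829 for independent calls (odds ratio 2.27, Fisher's exact test), and shared falls 1460 against 1050 (odds ratio 1.81).

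**Figure D4:**
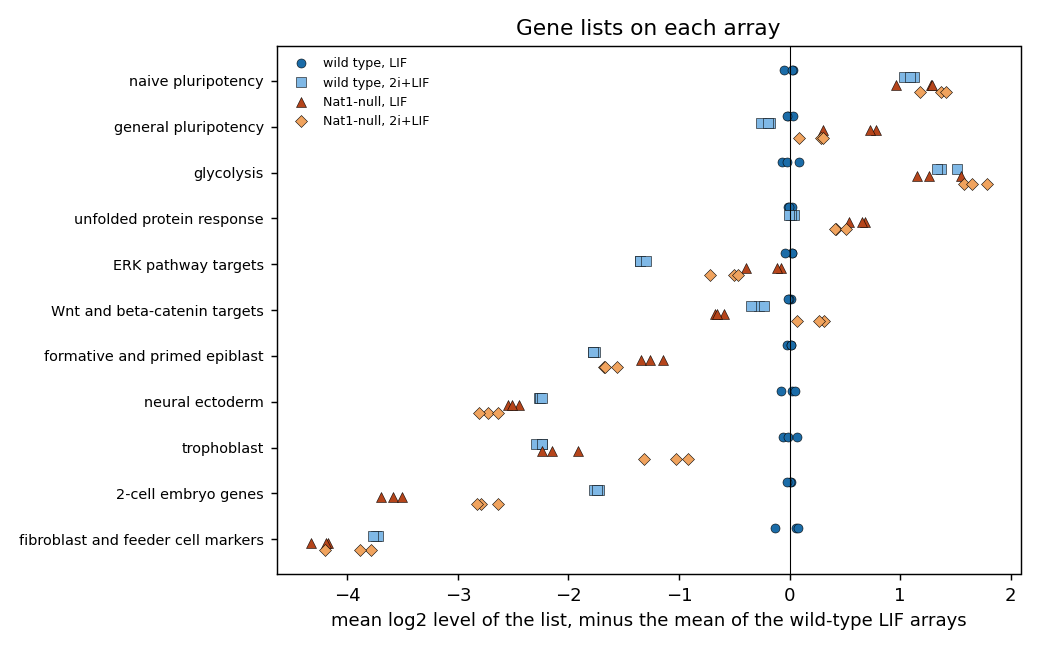
Mean log2 level of 11 gene lists on each of the 12 arrays, minus the mean of the wild-type LIF arrays; colour and shape give the group. The fibroblast and feeder cell list lies lower in the other groups, at -4.33 to -4.18 in Nat1-null LIF and -3.77 to -3.72 in wild-type 2i+LIF.

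The last comparison sets Nat1-null cells in LIF against wild-type cells in 2i+LIF, which asks how far the mutation and the inhibitors lead to the same state. The naive genes went both ways: Dppa3 was at -2.70 in Nat1-null cells, Esrrb (0.06, adjusted p = 0.64) did not pass, Tfcp2l1 was 1.79-fold lower in Nat1-null cells, Klf4 was higher by 1.05, and Nanog was 1.51-fold lower, a call that ended without scaling (adjusted p = 0.088). Several ERK targets and Cdx1 lay apart. Dusp6 was 8.49-fold and Egr1 6.20-fold higher in Nat1-null cells, with Spry4 at 4.27, Dnmt3l at 3.36 and Myc at 2.94, and Cdx1 was 23.5-fold lower. Zscan4c (-4.63) and the imprinted genes Snrpn (-4.96) and Plagl1 (-4.72) were lower in Nat1-null cells.

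ERK pathway targets had 13 of 22 genes up and 0 down (adjusted p = 2.4e-06; adjusted p = 0.25 with an estimated correlation). General pluripotency had 16 of 20 up and 0 down, with Utf1 at 2.09 and Sox2 at 1.20 (adjusted p = 2.4e-06; adjusted p = 0.44 with an estimated correlation). The unfolded protein response had 14 of 21 up and 3 down (adjusted p = 2.7e-06; adjusted p = 0.39 with an estimated correlation), and LIF and STAT3 targets had 12 of 18 up and 2 down (adjusted p = 3.8e-04; adjusted p = 0.44 with an estimated correlation). The 2-cell embryo genes had 11 of 16 down (adjusted p = 0.0057), with adjusted p = 0.22 with an estimated correlation and adjusted p = 0.20 among probes bright on all 12 arrays. DNA methylation machinery had 7 of 20 up and 2 down at adjusted p = 0.048, which ended with quantile normalization at adjusted p = 0.088, with an estimated correlation at adjusted p = 0.50, and without wild-type LIF replicate 1, any wild-type 2i+LIF array or Nat1-null LIF replicate 1 or 3, at adjusted p up to 0.075 without the last.

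The ATF4 and integrated stress response had 12 of 25 up, cholesterol synthesis 11 of 24 down, p53 targets 13 of 23 down and translation initiation factors 19 of 38 down. With an estimated correlation these had adjusted p = 0.44, 0.52, 0.44 and 0.52, and without scaling adjusted p = 0.064, 0.34, 0.054 and 1.0. Without Nat1-null LIF replicate 2 the ATF4, p53 and initiation factor lists had adjusted p = 0.065, 0.10 and 0.14, and the cholesterol list had adjusted p = 0.051 without replicate 1 and 0.055 without replicate 3 of that group. Ribosomal proteins had 60 of 73 down by a median of -0.25, with adjusted p = 0.90 after quantile normalization, adjusted p = 0.34 without scaling and adjusted p = 0.50 with an estimated correlation. Naive pluripotency (9 up, 9 down of 20), Wnt and beta-catenin targets (6 up, 9 down of 20), glycolysis (5 up, 8 down of 23), neural ectoderm (6 up, 7 down of 19) and fibroblast and feeder cell markers (0 up, 6 down of 18) were not called as lists. Adjusted over the list alone, the named counts changed by at most 1 gene per direction.

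Between these groups 12688 genes passed, 5353 higher and 7335 lower in Nat1-null LIF. By at least 2-fold, 1263 rose and 1997 fell, a total of 3260 that became 1800 with normexp background correction and 1920 among probes bright on all 12 arrays. Without scaling the median moved by 0.41 and 83.7% of called genes were higher, against 42.2%. The mean Euclidean distance between arrays was 137 for this pair of groups, 213 between wild-type and Nat1-null cells in LIF, 170 between wild-type LIF and wild-type 2i+LIF, 125 between the genotypes in 2i+LIF and 119 between the Nat1-null groups.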

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

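The genes and lists given first were called by a test of the interaction itself, and 3 patterns across genes follow. The interaction holds the difference between the wild-type groups, which lie on different slides, so it cannot be told apart from the slide. For a gene high in wild-type LIF alone, such as Acta2, it reflects that level. The lists, the naming rule, the comparisons, most of the alternatives and the counts of other splits were set before the data were examined. Chosen only after the result was seen were the tests of shared arrays, of dim probes, of fibroblast RNA, of dilution, of cells leaving pluripotency, and of the 2i differences within single lists.

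The interaction was called for 12166 genes and, by at least 2-fold, for 4973. It was positive, meaning that with 2i the gene fell less or rose more in Nat1-null cells, or rose there and fell in wild-type cells, for Dppa3 (6.90), Fgf5 (6.29), Egr1 (4.81), Dnmt3b (3.21), Axin2 (2.99), Dnmt3l (2.92), Lefty1 (2.50), Myc (2.25), Lefty2 (1.38), Otx2 (1.32), Dusp6 (0.76), Map3k3 (0.50) and Eif4g2 (0.32). The Fgf5 value rests on wild-type 2i+LIF levels at background, and the Egr1 value on levels in that group near it. The Myc call ended without any wild-type LIF array, wild-type 2i+LIF replicate 1 or 3, or Nat1-null 2i+LIF replicate 1 or 3, at adjusted p up to 0.064 without the last. It was negative for Esrrb (-2.51), Gata6 (-2.41), Tfcp2l1 (-2.32), Prdm14 (-2.24), Klf4 (-2.13), Nanog (-1.82), Pou5f1 (-1.42), Sox1 (-1.23), Klf2 (-1.20), Sox2 (-1.06), Etv5 (-0.96), Etv4 (-0.78) and Zfp42 (-0.61, which ended without scaling at adjusted p = 0.26). The largest positive values among bright genes were those of Acta2 (9.33), Rhox6 (7.59), Acta1 (7.50), Krt18 (7.14) and Rhox9 (6.86), besides Dppa3. The largest negative values were those of Ndufa4l2 (-5.07), Grin2c (-4.96), Tal1 (-4.88), Vax2os (-4.88), Gm9918 (-4.79) and Polr3gl (-4.50).

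Lists with a positive shift were fibroblast and feeder cell markers (adjusted p = 1.3e-06), trophoblast (3.4e-06), 2-cell embryo genes (1.0e-05), formative and primed epiblast (8.9e-04), neural ectoderm (8.9e-04), p53 targets (0.0013), Wnt and beta-catenin targets (0.0013) and ERK pathway targets (0.025). Lists with a negative shift were glycolysis (5.5e-06), naive pluripotency (2.7e-05) and LIF and STAT3 targets (0.0074). With an estimated correlation 2 of these 11 passed, fibroblast and feeder cell markers (adjusted p = 0.030) and 2-cell embryo genes (adjusted p = 0.022).

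Of 100 labelings of the 12 arrays for the interaction, the real one included, 1 gave as many called genes (12166, with 7465 the highest other). By at least 2-fold, 1 gave as many genes (4973 against 3975). The labelings moved all 12 arrays freely, so group differences of any kind entered the spread of the mixed groups. The real labeling would then rank high with or without an interaction, so the rank does not exclude chance for these counts. For the number of lists, 18 of 100 gave at least the real 11, with 13 the highest other, so chance cannot be excluded. A comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. Real counts of called genes against the highest other split were 16349 and 0 (genotype in LIF), 10666 and 0 (genotype in 2i+LIF), 15227 and 0 (2i in wild type), 9079 and 25 (2i in Nat1-null) and 12688 and 0 (Nat1-null LIF against wild-type 2i+LIF). By at least 2-fold they were 6360 and 0, 2656 and 0, 4690 and 0, 1958 and 18, and 3260 and 0. Counts of shifted lists were 11 and 11 (2 of 10 splits), 12 and 11, 12 and 10, 14 and 12, and 11 and 10, the last 4 with 1 of 10 splits each.

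Nat1-null LIF cells and wild-type 2i+LIF cells differed from wild-type LIF cells in the same direction, with r = 0.790 across genes. Simulated unchanged pairs that shared arrays, made from residuals of arrays drawn from all groups, can also reach this value (up to 0.895). Sharing of the wild-type LIF arrays is argued against as the whole cause by a covariance of 1.09, above the highest of 100 simulated unchanged pairs (0.0688). Over genes bright on all 12 arrays r was 0.731, which simulated unchanged pairs can also reach (up to 0.946). The covariance over these genes was 0.555, against at most 0.0332 in those pairs. This covariance argues against dim probes as the whole cause. An error in hybridising, washing or scanning slide 1 that acts on probes would, on its own, leave different probes of a gene unrelated. For the mean of the 2 differences from wild-type LIF, 2 probes of the same gene gave r = 0.784 over 3069 genes. Probes of different genes gave 0.0194. This argues against such an error as the whole cause, and a smaller one on top of transcript differences is not excluded. A difference in culture or RNA handling of the wild-type LIF samples that coincides with slide 1 stays open, because no other group is on that slide. A like effect of the mutation and of 2i is the biological hypothesis that may account for the pattern, and the design cannot separate it from such a difference.

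The 2i differences of wild-type and of Nat1-null cells were nearly unrelated across genes (r = 0.0541). An effect of the row on slide 3 cannot be told apart from that of 2i: within a row r was 0.101, but that rests on a single Nat1-null LIF array. A candidate explanation is that for part of the genes Nat1-null cells in LIF start from another level: r was 0.405 over 8114 genes not called different between genotypes in LIF, and -0.0841 over 6360 genes different by at least 2-fold. The first value passes its bound of 0.4, set before the test, by a margin too small to carry weight, and genes picked for like starting levels favour a positive r. By list, r was 0.667 over 40 ERK and Wnt target genes and -0.0702 over 43 naive pluripotency and glycolysis genes, and the slides of the wild-type groups stay confounded with medium.

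Most fibroblast markers and many neural ectoderm and trophoblast genes were higher in wild-type LIF cells than in the other groups. The endoderm list was not called by genotype in LIF (5 up, 9 down of 20, camera adjusted p = 0.37). Its member Gata6 was higher in Nat1-null LIF by 2.77, against the direction of most called members. The plates were coated with gelatin, and the labels name no feeder cells. Of neural ectoderm and trophoblast genes, 13 of 36 were at least 8-fold higher in wild-type LIF than in both wild-type 2i+LIF and Nat1-null LIF. The same held for 11 of 18 fibroblast markers. This cannot decide whether fibroblast RNA alone is the cause. It assumes that fibroblasts do not use those lists, which hold Vim, Nes, Krt8 and Krt18, and that was not checked. Acta2 was at 6.30 in wild-type LIF. Fn1, the exception among abundant fibroblast genes, was lower in wild-type LIF (5.79) than in Nat1-null LIF (6.69). Dilution of stem cell RNA as the only difference would lower all pluripotency genes in wild-type LIF. Against wild-type 2i+LIF, 9 of 40 were higher, among them Dppa3, Utf1 and Lin28a, while 20 were lower. This argues against dilution as the only difference. Dilution next to a change of these genes with 2i stays open, because the comparison holds both. Cells leaving pluripotency in several directions might account for the markers, but 0 arrays of another group share slide 1, so this cannot be told apart from a difference in handling of those 3 samples. A mixture of several kinds of differentiated cells was not tested.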

How the results depend on the processing

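Added after the data were seen was the slide row as a block, which rests on a single Nat1-null LIF array; the other alternatives here were planned. Counts of called genes stayed within 1.5 times the main count in each alternative, except for 2i in Nat1-null cells with its 6 arrays alone (4846 of 9079). The main fit shares 1 spread over all groups, and Nat1-null replicates differed more than wild-type ones, so the shared spread favours calls in this comparison. Fewer arrays also give a less certain spread. How much each adds to the drop was not tested. Counts by at least 2-fold fell by more with normexp background correction and with probes bright on all 12 arrays, in that order: 4215 and 3735 for genotype in LIF, 1218 and 1411 for genotype in 2i+LIF, 2638 and 2569 for 2i in wild type, 974 and 1157 for 2i in Nat1-null cells, 3250 and 3006 for the interaction, and 1800 and 1920 for Nat1-null LIF against wild-type 2i+LIF. The brightness filter tests fewer genes; for normexp the cause was not tested. With the replicate block 16229 genes were called for genotype in LIF (16349 without it). Leaving out any single array moved no count of genes by more than 1.5 times.

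The correlation of genotype in LIF with 2i in wild type was 0.767 with no filter, 0.730 with bright probes and 0.761 to 0.802 when leaving out 1 array. That of the genotype differences was 0.479 with normexp, 0.438 with quantile normalization, 0.370 with no filter, 0.449 with bright probes and 0.377 to 0.419 when leaving out 1 array. That of the 2i differences was 0.0789 with normexp, 0.0823 with quantile normalization, 0.0976 with bright probes, 0.101 with the slide row as a block and 0.0220 to 0.0696 when leaving out 1 array. The cause was not tested.

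Of 150 list tests 71 were called, 9 with an estimated correlation. Apart from that setting 45 calls held in every alternative and 26 were lost in at least 1. Ribosomal proteins reversed for 2i in wild type without scaling (adjusted p = 0.0056), which shifts all genes. Of 753 gene values 713 were called, 625 of them in every alternative. Without scaling, values reversed to -0.16 for Rpl13, -0.068 for Rpl3, -0.038 for Rps15 and -0.15 for Rps9 (2i in wild type), -0.021 for Nanog (2i in Nat1-null), and 0.084 for Rpl28, 0.042 for Rpl3 and 0.067 for Rps15 (interaction). With the mean of its probes Rpl13a reversed to -0.14 (genotype in 2i+LIF); the cause was not tested. A list whose direction turned without a call was counted as lost, not as reversed. Slide as a random or fixed block was not run, because each group lies within 1 slide and the contrasts between slides cannot be separated from it. Signal over background limits what dim genes can show.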

Other observations

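The lists in this part and the genes named were chosen after the data were seen. Imprinted genes, which are expressed from one parental copy, were lower in Nat1-null than in wild-type cells in LIF: 23 of 25 tested genes fell and 1 rose (adjusted p = 9.4e-09; adjusted p = 0.0042 with an estimated correlation). In wild-type cells 2i lowered 19 of 25 and raised 3 (adjusted p = 4.6e-07; adjusted p = 0.0095 with an estimated correlation). H19, a maternally expressed noncoding RNA, went from 3.76 in wild-type LIF to -2.40 in wild-type 2i+LIF and -4.06 in Nat1-null LIF. Some of the genes were low in Nat1-null cells in both media: Snrpn was at -6.12 against wild type in LIF and -4.92 in 2i+LIF, Kcnq1ot1 at -5.57 and -3.85, and Mest, a paternally expressed gene, at -3.89 and -2.24. Dlk1, a Notch-family ligand, was well above background on all wild-type arrays (1.55 in LIF, -1.93 in 2i+LIF) and on 0 of 6 Nat1-null arrays. In 2i+LIF the imprinted list as a whole was not called (12 down, 6 up, adjusted p = 0.17), and its interaction was upward in 19 of 25 (adjusted p = 4.7e-09; adjusted p = 0.0042 with an estimated correlation). The fibroblast and feeder cell markers fell in the same 2 comparisons (medians -4.17 and -4.29) and were not called by genotype in 2i+LIF (adjusted p = 0.63), so the falls against wild-type LIF are not separated from whatever sets those 3 samples apart. The lists of this part were not run under other scalings. The list named smooth muscle contractile genes shares Acta2 and Tagln with the fibroblast list and also holds cardiac actin Actc1. With 2i in wild type 13 of 13 members were lower (adjusted p = 2.8e-10, or 0.0030 with an estimated correlation). In Nat1-null LIF 13 of 13 were lower (adjusted p = 1.1e-08, or 0.0042 with an estimated correlation). The p-values of lists chosen after the data were seen describe a pattern and do not test it.

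Hox genes pattern the body axis, and none of their list calls passed with an estimated correlation. Of the posterior paralogs 9 to 13, 2i raised 11 of 13 in wild-type cells (adjusted p = 1.2e-05; adjusted p = 0.0505 with an estimated correlation) and 10 of 13 in Nat1-null cells (adjusted p = 1.4e-05; adjusted p = 0.13 with an estimated correlation), with 0 lowered in either. Hoxc13 rose by 3.97 and 0.69, and Hoxb13 by 2.90 and 1.91. Of paralogs 1 to 8, 2i lowered 13 of 20 in wild-type cells (adjusted p = 0.0025; adjusted p = 0.16 with an estimated correlation), among them Hoxb2 and Hoxb4 at -4.79 and -2.06, and 14 of 20 were lower in Nat1-null than in wild-type cells in LIF (adjusted p = 3.8e-04; adjusted p = 0.12 with an estimated correlation). Like those of imprinted genes, the differences of Hox and Y-linked genes from wild-type LIF are not separated from whatever sets those 3 samples apart. Paralogs 1 to 8 were not called with 2i in Nat1-null cells (7 up, 1 down, adjusted p = 0.29) or by genotype in 2i+LIF (5 up, 7 down, adjusted p = 0.96). Of the Y-linked genes, Ddx3y and Eif2s3y were well above background on all 12 arrays, and Uty, Zfy1, Zfy2 and Usp9y were so on at most 2 of 3 arrays of each Nat1-null group; 6 of 6 were lower in Nat1-null than in wild-type LIF cells (adjusted p = 0.0044; adjusted p = 0.12 with an estimated correlation), with Ddx3y at -1.10 and Eif2s3y at -1.22. In 2i+LIF 3 of 6 were lower in Nat1-null cells and the list was not called (adjusted p = 0.18); its interaction had adjusted p = 0.012, and adjusted p = 0.18 with an estimated correlation.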
